A study of Mus musculus with 12 samples.

How the data were processed

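Sorted splenic eosinophils with high side scatter and green fluorescence, from mice that overproduce interleukin-5 and carry a fluorescent interleukin-4 reporter, were cultured for 4 h per the labels' protocols. The 4 groups received an isotype control antibody, 5 µg/mL of an antibody against Siglec-F (an inhibitory sialic acid-binding receptor of eosinophils), 10 ng/mL of interleukin-33 (IL-33, an alarmin cytokine), or both stimuli. Each group had 3 libraries, 12 in all. The labels do not state whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

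The authors deposited raw counts per gene for 54532 genes, whole numbers per the file headers and values. The authors also deposited normalized counts, a signal equal to the count divided by 1 size factor per library. Dividing each library's values by its smallest step gave whole reads for 100% of the nonzero values, within a relative tolerance of 1e-06, and these reads equalled the raw counts. The count test on the recovered reads, added after the data were seen, thus ran on the same values and had to call the same numbers. These were 322 genes for IL-33 against isotype, 1437 for both stimuli against isotype and 643 for both stimuli against the antibody alone. Per the submitters' processing notes the reads were placed on mm10, and fastp, STAR 2.6.1d, FastQC 0.11.8, featureCounts 1.5.0-p3 and DESeq2 were used. The annotation release and the strand setting of the counting are not given in the sources used here. Reads from overlapping or antisense genes can therefore not be told apart, and near-identical copies such as the Bcl2a1 and Ear genes and Hspa1a with Hspa1b are uncertain.

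Total counts ran from 11686603 to 17137988 per library. Genes that passed the expression filter numbered 14547. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group, all 12 libraries in 1 fit and no replicate block. Benjamini-Hochberg adjustment was applied within each comparison, and genes with an adjusted p under 0.05 were called. Calls of at least 2-fold were counted as well. CPM, the reads of a gene as a rate within its library, were computed from the deposited counts with the TMM factors. Gene identifiers and coordinates are those of the authors' table (mm10). Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. The 6 comparisons were fixed before the data were examined. The last is the interaction, the antibody effect with IL-33 minus that without it.

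Gene lists, 29 in number and 9 of them markers of other cell types, were fixed at the same time. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 174 tests, again with a correlation estimated per list, and with fry. No list call remained at an estimated correlation. For IL-33 against isotype the estimates ran from -0.17 for stroma and endothelium markers to 0.65 for proliferation genes. They were 0.43 for the NF-kB list, 0.41 for chemokines and 0.55 for heat shock and oxidative stress genes. Where the estimate lies far above 0.01, the camera p-values at the preset correlation may be far too small. Members were counted over all genes and adjusted over the list alone. Of 586 listed symbols, 583 were in the table.

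The named genes follow a rule that was fixed at the same time as well. For each comparison it takes the 8 genes with the most positive and the 8 with the most negative log2 fold change among called genes with a mean of at least 5 CPM, a symbol that is not a predicted model or pseudogene, and no overlap between the libraries of the 2 groups (not asked for the interaction). The mean is over 12 libraries. The rule adds up to 4 called members of each list with the largest change. It also lets a list gene without a call be named with its values, and such genes could be picked after those were seen. It always adds Siglecf, Il1rl1, Il1rap, Il5ra, Ccr3, Epx, Prg2, Il4, Il13, Il6, Csf2, Ccl3 and Ccl17.

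The tests across genes were run on simulated counts with 200 changed genes. For IL-33 against isotype, over 14156 genes, edgeR called 38.8% of genes changed 2-fold, 71.6% of those changed 4-fold and 81.8% of those changed 8-fold, and 5.19% of its calls were unchanged genes. In that same simulation DESeq2 1.42.0 gave 17.9% unchanged genes among its calls. The simulation drew genes independently, each with the same spread in all groups. The real groups differed, with a median SD of log2 CPM of 0.150 for isotype and 0.326 for both stimuli. These shares therefore need not hold for the real data.

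Whether equal replicate numbers pair libraries was checked from the correlation of their deviations from group means, against a fixed threshold. For IL-33 against isotype the correlations were 0.24, 0.24 and 0.17, all over 0.1, so the numbers were taken as pairing those libraries. The pairing comes from the data and not from the labels. Libraries with unlike numbers were not set beside them, so the check is weak, and the main fit did not use the pairing. Replicates of a group differed beyond sampling noise in each pair, with a chi-square of 14.3 to 115 per degree of freedom. Other settings were DESeq2, 2 other scalings, 2 other filters, fits of only the groups compared, a replicate block and leaving out each library. Added after the data were seen were fits without libraries 2 and 3 of the combined group, limma voom with sample quality weights, a fit of 9 libraries, the block in the fit of only the groups compared, and fits with each library's trend on gene length and GC content removed by splines with 4 degrees of freedom.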

Results

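Gene expression was measured by RNA sequencing in eosinophils kept for 4 h with an isotype control antibody, an anti-Siglec-F antibody, IL-33, or both stimuli, in 3 libraries each. Total counts lay between 12046727 and 14636985 in the isotype group and between 11686603 and 15058611 with the antibody. They lay between 12140747 and 15686225 with IL-33 and between 12663407 and 17137988 with both. Libraries 2 and 3 of the combined group stood apart: 15555 and 29990 genes had at least 1 count there, against 19138 to 24485 in the other libraries. Ribosomal protein genes took 3.23% and 3.70% of their counts, against 1.7% to 2.6% elsewhere. The median SD of log2 CPM within a group, over 8262 genes, was 0.150 for isotype, 0.170 for the antibody, 0.204 for IL-33 and 0.326 for both stimuli.

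**Figure D1:**
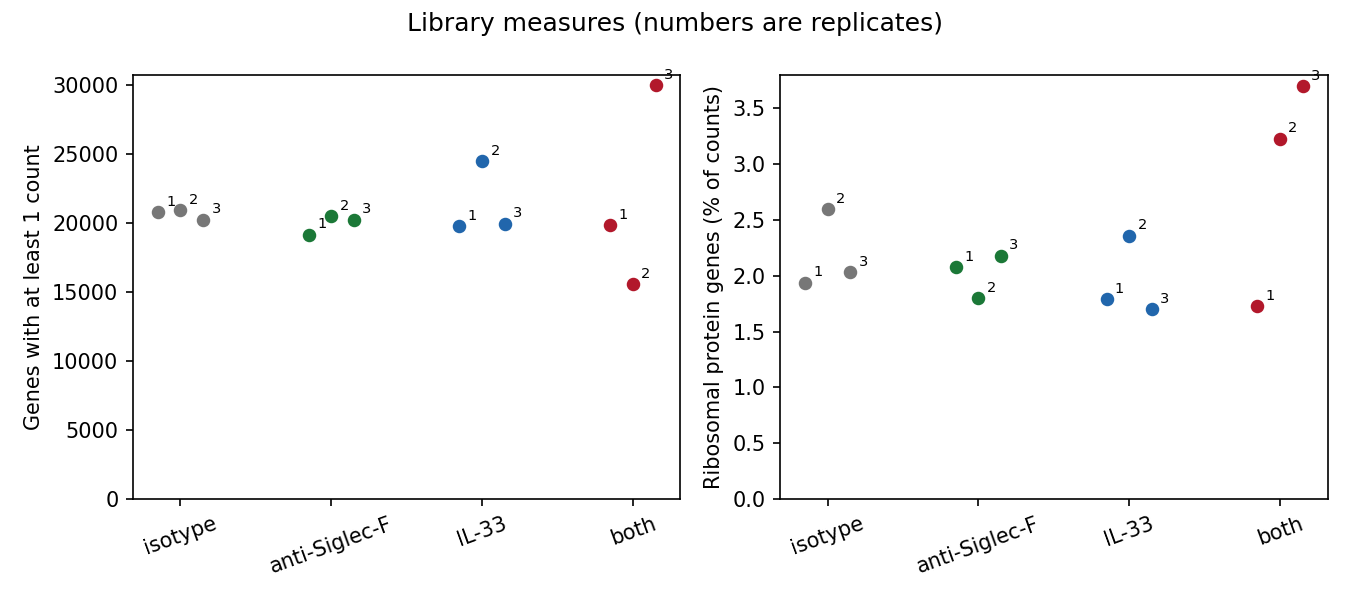
Genes with at least 1 count (left panel) and the percent of counts in ribosomal protein genes (right panel) for each library, with points numbered by replicate and coloured by group. Libraries 2 and 3 of the combined group lie at 15555 and 29990 genes and at 3.23% and 3.70%.

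IL-33 against isotype asked what the cytokine changed by itself. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), which encodes interleukin-6, rose from 2.30 ± 0.564 to 209 ± 125 CPM (SD, n = 3), a log2 fold change of 6.49 (SE 0.661). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), which encodes interleukin-1 beta, rose from 15.9 ± 2.49 to 1160 ± 688 CPM. Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), the inducible cyclooxygenase of prostaglandin synthesis, rose by a log2 fold change of 6.59. The chemokine gene Ccl3 rose by 5.25 and the type 2 cytokine gene Il13 by 3.45. Among genes that fell, Mettl7a1 went from 129 ± 16.6 to 36.1 ± 9.77 CPM and Fbxo31 from 50.2 ± 5.70 to 15.2 ± 3.27 CPM. In edgeR 322 of 14547 genes were called, 213 higher and 109 lower, and 224 of them changed at least 2-fold.

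Of 29 measured NF-kB pathway members and feedback genes, 13 rose and 16 were not called, and 23 were higher when adjusted over the list alone (camera adjusted p = 1.23e-48, and adjusted p = 0.152 with an estimated correlation). Nfkbia, an inhibitor of NF-kB that NF-kB itself induces, rose from 76.6 ± 5.43 to 573 ± 185 CPM, and Nfkbiz and Nfkb2 had log2 fold changes of 2.83 and 2.12. Of 22 cytokines and growth factors 6 rose, and 10 when adjusted over the list alone (camera adjusted p = 4.60e-18, and adjusted p = 0.152 with an estimated correlation). Of 13 chemokines 6 rose, among them Cxcl2 and Ccl4 with log2 fold changes of 5.47 and 4.76. When adjusted over the list alone 8 chemokines rose and 1 fell (camera adjusted p = 1.20e-11, and adjusted p = 0.200 with an estimated correlation). Survival genes of the BCL2 and IAP families rose in 5 of 15 cases, and in 9 when adjusted over the list alone (camera adjusted p = 5.13e-11, and adjusted p = 0.152 with an estimated correlation). Bcl2l1, which encodes Bcl-xL, rose from 106 ± 14.5 to 263 ± 40.4 CPM. Heat shock and oxidative stress genes rose in 4 of 18 cases, and in 8 when adjusted over the list alone (camera adjusted p = 1.50e-07, and adjusted p = 0.395 with an estimated correlation). Those 4, Hmox1, Slc7a11, Srxn1 and Sqstm1, each lost the call in 5 of 6 fits with 1 library left out. The fry p for movement on balance in 1 direction was 0.000204 for the NF-kB list and 0.00166 for cytokines and growth factors. It was 0.00583 for chemokines, 0.00104 for survival genes and 0.0501 for heat shock and oxidative stress genes.

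Of 19 IL-33 receptor signalling genes 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00321, and adjusted p = 0.395 with an estimated correlation). It was Irak3, a brake on signalling from receptors of the interleukin-1 family, which went from 51.9 ± 6.10 to 338 ± 48.3 CPM (edgeR adjusted p = 1.50e-05). Of 22 inhibitory receptors and their phosphatases 3 rose, and 6 when adjusted over the list alone (camera adjusted p = 0.000454, and adjusted p = 0.301 with an estimated correlation). Siglece, a sialic acid-binding inhibitory receptor, rose from 219 ± 25.3 to 706 ± 147 CPM. The other members that rose, Ceacam1 and Pilra, lost their calls in 5 and 6 of 6 fits with 1 library left out. Immediate early genes rose in 6 of 33 cases, and when adjusted over the list alone 15 rose and 3 fell (camera adjusted p = 3.96e-06, and adjusted p = 0.396 with an estimated correlation). The 4 called members with the largest change, Egr2, Atf3, Nr4a1 and Ier3, each lost the call in 5 of 6 fits with 1 library left out. Ier3 also lost it with the replicate block (edgeR adjusted p = 0.0637). Of 26 adhesion and chemoattractant receptors 2 rose and 3 fell, and 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.848). Cd69, an activation marker of that list, rose by a log2 fold change of 3.03.

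Some receptor and granule protein genes named in advance were not called. Il1rl1, which encodes the IL-33 receptor chain ST2, had a log2 fold change of 0.22 (edgeR adjusted p = 0.740), Siglecf of -0.33 (adjusted p = 0.502), Ccr3 of -0.31 (adjusted p = 0.449) and Il5ra of -0.47 (adjusted p = 0.565). Epx and Prg2, which encode granule proteins, had log2 fold changes of -0.26 and -0.51, with SE of 0.672 and 0.691. Il4 had 0.57 (adjusted p = 0.305), Il1rap 0.22 and Ccl17 0.20. Csf2 had 4 counts in IL-33 library 2 and 0 in the other libraries of both groups, so it was not tested. Il6 stood at 330, 216 and 79.8 CPM in IL-33 libraries 1, 2 and 3.

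Leaving out 1 library moved the count to 116, 135 and 127 without isotype libraries 1, 2 and 3, to 124 and 175 without IL-33 libraries 1 and 2, and to 488 without IL-33 library 3. Of 60 named genes called in this comparison 24 kept their call whichever library was left out. They include each gene named above as rising or falling, apart from those whose losses are given there. With the replicate block and only these groups 1235 genes were called, and limma voom with quality weights called 2089, 1002 higher and 1087 lower.

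Among marker lists of other cells, 3 of 14 monocyte and macrophage genes rose with IL-33, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.232, and adjusted p = 0.862 with an estimated correlation). Its median log2 fold change was -0.18, while its mean of 0.44 and the camera test pointed up. The 3 genes were Csf1r, Spic and Hmox1, with log2 fold changes of 0.96, 3.65 and 3.24. Csf1r kept its call whichever library was left out. Spic lost it without isotype library 1 or 3 or IL-33 library 1, and Hmox1 in each case but the fit without IL-33 library 3 (edgeR adjusted p up to 0.0674 and 0.124, both without isotype library 3). Of 8 dendritic cell genes 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0230, adjusted p = 0.514 with an estimated correlation and 0.124 with the strict expression filter). It was Batf3, which kept its call only when IL-33 library 3 was the library left out (edgeR adjusted p up to 0.170, without IL-33 library 1). No member was called of the neutrophil markers (camera adjusted p = 0.0866), basophil and mast cell (0.701), T cell and ILC2 (0.227), B and plasma cell (0.835), erythroid (0.233), megakaryocyte and platelet (0.835) and stroma and endothelium markers (0.393). The median and the mean differed in sign for B and plasma cell markers, with 0.01 and -0.04, and for megakaryocyte and platelet markers, with -0.20 and 0.06.

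**Figure D2:**
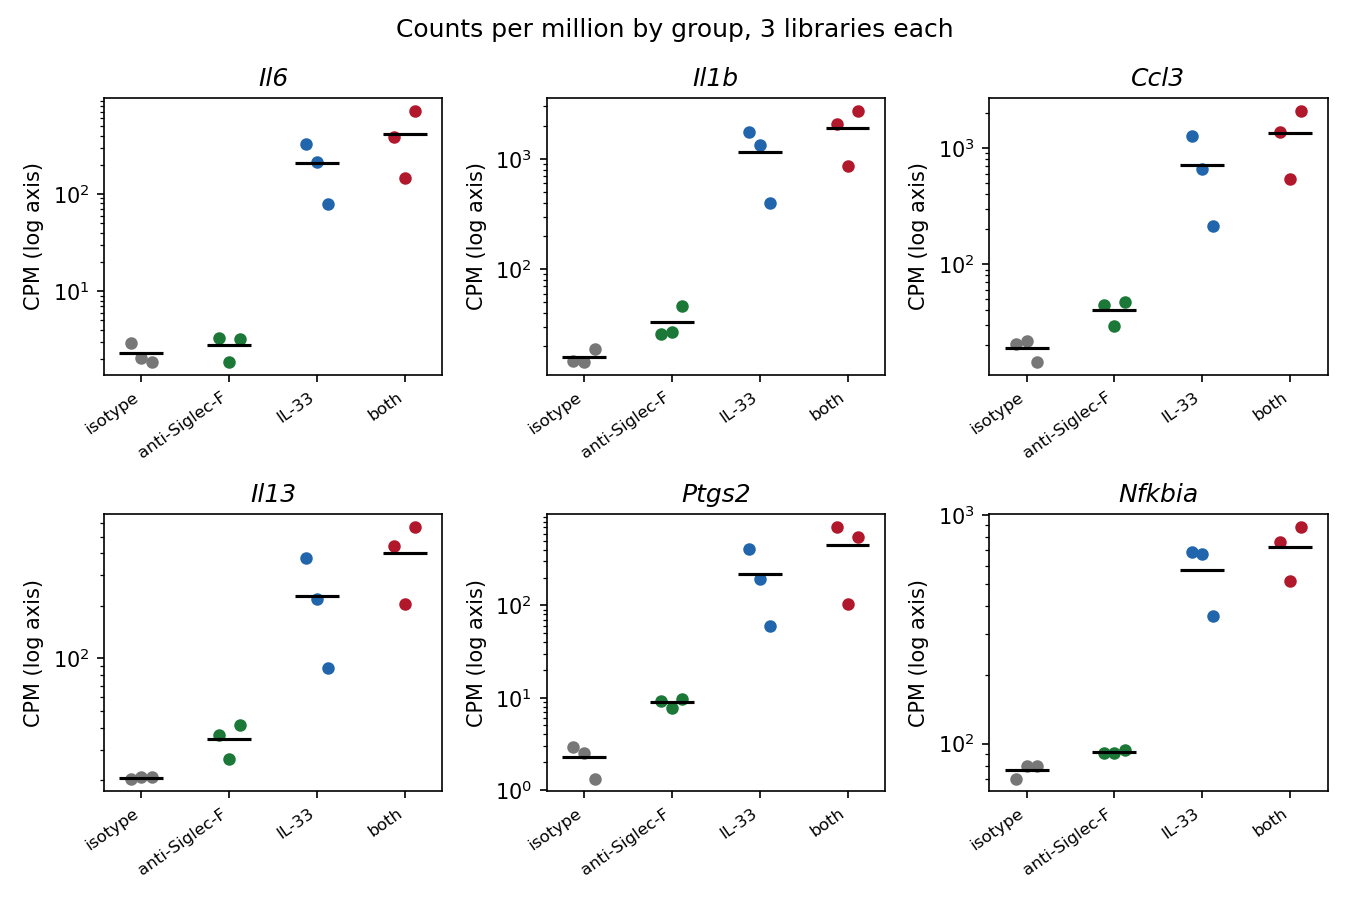
Reads of 6 genes as CPM on a log axis in the 4 groups; points are libraries and the black line is the group mean of 3 libraries. Il6 lies at 1.85 to 3.29 CPM in the 6 libraries without IL-33 and at 79.8 to 723 CPM in the 6 libraries with it.

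The antibody alone against isotype asked what engaging Siglec-F changed without IL-33. Siglecf (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531) stood at 878 ± 77.7 CPM in the isotype group and 908 ± 138 CPM with the antibody (SD, n = 3), a log2 fold change of 0.05 (edgeR adjusted p = 1). Ccl3 had a log2 fold change of 1.10 (SE 0.538), Il13 of 0.74 (SE 0.433), Il4 of 0.47 and Il6 of 0.27, each with an edgeR adjusted p of 1. Ccr3, Il5ra, Epx, Prg2, Il1rl1, Il1rap and Ccl17 lay between -0.71 and 0.27. No gene was called by edgeR, and 370 genes had an unadjusted p under 0.05 where 727 are expected by chance. That number was 1059 with only these groups, 767 in the fit of 9 libraries without the combined group, 791 without libraries 2 and 3 of that group and 1751 with limma voom. DESeq2 called 12 genes, limma voom with sample quality weights 10, edgeR with only these groups 20 and edgeR without the expression filter 70. The 12-library fit shares 1 estimate of spread per gene over all groups. The median SD was 0.150 and 0.170 in these groups and 0.326 in the combined group, so its p-values may be too large here. The 0 calls thus do not show that the antibody changed nothing.

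Some gene lists were called by camera at its preset correlation although no member was called over all genes. Heat shock and oxidative stress genes had positive log2 fold changes in 15 of 18 cases, with a median of 0.43, and 0 were called when adjusted over the list alone (camera adjusted p = 1.07e-09, and adjusted p = 0.337 with an estimated correlation). Cytokines and growth factors had positive values in 17 of 22 cases, and 1 was called when adjusted over the list alone (camera adjusted p = 1.05e-07, and adjusted p = 0.302 with an estimated correlation). Chemokines had positive values in 11 of 13 cases, with a median of 0.94 (camera adjusted p = 0.000114, and adjusted p = 0.395 with an estimated correlation). In all 9 of 29 lists were called, and 0 with an estimated correlation. For movement on balance in 1 direction, the fry p of these 9 lists ran from 0.0641 for ribosome biogenesis and MYC targets to 0.391 for glycolysis and hypoxia genes. For movement in either direction it was 0.0423 for cytokines and growth factors, 0.0317 for inhibitory receptors and their phosphatases, and above 0.05 for the other 7.

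Both stimuli against isotype asked what the combination changed. Il6 rose from 2.30 ± 0.564 to 418 ± 291 CPM (SD, n = 3), Il1b to 1890 ± 956 CPM and Il13 from 20.7 ± 0.205 to 404 ± 184 CPM. Padi2, a peptidylarginine deiminase, fell from 115 ± 12.9 to 26.3 ± 12.9 CPM, and Itgb7, the integrin beta 7 chain, from 679 ± 39.8 to 212 ± 41.3 CPM. In edgeR 1437 genes were called, 796 higher and 641 lower, 766 of them at least 2-fold.

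Glycolysis and hypoxia genes rose in 15 of 25 cases, and in 16 when adjusted over the list alone (camera adjusted p = 1.02e-08, and adjusted p = 0.368 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase induced in hypoxia, rose from 27.1 ± 3.27 to 141 ± 53.7 CPM, and the glycolytic enzyme genes Pfkl and Tpi1 had log2 fold changes of 2.31 and 2.08. Heat shock and oxidative stress genes rose in 13 of 18 cases, and in 15 when adjusted over the list alone (camera adjusted p = 4.62e-14, and adjusted p = 0.301 with an estimated correlation). Hmox1, heme oxygenase 1, rose from 103 ± 45.2 to 1630 ± 913 CPM. Of 29 NF-kB pathway members and feedback genes 22 rose, and 23 when adjusted over the list alone (camera adjusted p = 1.43e-30, and adjusted p = 0.152 with an estimated correlation). Survival genes rose in 9 of 15 cases, and in 10 when adjusted over the list alone (camera adjusted p = 2.98e-12, and adjusted p = 0.152 with an estimated correlation). Bcl2a1b, a BCL2 family gene with near-identical copies, rose from 14.3 ± 1.39 to 72.7 ± 27.1 CPM.

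Siglecf had a log2 fold change of -0.51 (edgeR adjusted p = 0.0999), Il1rl1 of 0.43 (adjusted p = 0.181) and Ccl17 of 1.73 (adjusted p = 0.0984). Ccr3 had -0.21, Il5ra -0.54, Epx 0.07, Prg2 0.68, Il4 0.45 and Il1rap 0.33, none called. Among marker lists of other cells, monocyte and macrophage genes rose in 4 of 14 cases, and in 5 when adjusted over the list alone (camera adjusted p = 0.00710, adjusted p = 0.545 with an estimated correlation and 0.0802 on log2 CPM with length and GC trends removed). They were Hmox1, Spic, Csf1r and Slc40a1, the last with an edgeR adjusted p of 0.0264. Slc40a1 lost its call without isotype library 1, 2 or 3 (adjusted p up to 0.119, without library 3) and without library 1 or 3 of the combined group. Stroma and endothelium genes rose in 2 of 3 cases, also when adjusted over the list alone (camera adjusted p = 0.0199, adjusted p = 0.299 with an estimated correlation and 0.0550 with the strict filter). They were Pecam1, which lost its call in 1 of 6 fits with 1 library left out, and Acta2, which lost it in 4 of 6, without libraries 2 and 3 of the combined group and with only the groups compared. Basophil and mast cell markers rose in 1 of 10 cases (camera adjusted p = 0.500) and dendritic cell markers in 1 of 8 (0.0871). No member was called of 15 neutrophil markers (0.961), 17 T cell and ILC2 markers (0.386), 14 B and plasma cell markers (0.278), 7 erythroid markers (0.227) and 4 megakaryocyte and platelet markers (0.888).

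The count of 1437 genes became 651, 521 higher and 130 lower, without libraries 2 and 3 of the combined group and 738, 482 higher and 256 lower, with only the 2 groups. It was 515, 866 and 518 without isotype libraries 1, 2 and 3, and 2916 and 934 without libraries 1 and 3 of the combined group. The main fit shares 1 estimate of spread per gene over all groups. The median SD was 0.150 for isotype and 0.326 for both stimuli, so its p-values and SE may be too small here.

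Both stimuli against IL-33 asked what the antibody added to the cytokine. Glycolysis and hypoxia genes had positive log2 fold changes in 20 of 25 cases, with a median of 0.65, and 15 were higher when adjusted over the list alone (camera adjusted p = 1.26e-09, and adjusted p = 0.337 with an estimated correlation). Tpi1 had a log2 fold change of 1.59 (SE 0.319), Ldha, lactate dehydrogenase A, of 1.15 (SE 0.238) and Egln3 of 1.17 (SE 0.252), each with an edgeR adjusted p of 0.191 over all genes. In the combined group's libraries 2 and 3, ribosomal protein genes took 3.23% and 3.70% of the counts. Heat shock and oxidative stress genes had positive values in 18 of 18 cases, and 3 were higher when adjusted over the list alone (camera adjusted p = 8.48e-07, and adjusted p = 0.395 with an estimated correlation). Il6 had a log2 fold change of 1.00 (SE 0.499), Il13 of 0.83 (SE 0.419) and Ccl3 of 0.90 (SE 0.521). Siglecf had -0.18, Il1rl1 0.21, Ccr3 0.10, Il4 -0.12 and Ccl17 1.54, none called.

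For both stimuli against IL-33 camera also called marker lists of other cells, with 0 members called over all genes. T cell and ILC2 markers had positive log2 fold changes in 1 of 17 cases, with a median of -0.90, and 0 were called when adjusted over the list alone (camera adjusted p = 0.00863, adjusted p = 0.735 with an estimated correlation and 0.0822 with the strict filter). They summed to 60, 175 and 41.8 CPM in IL-33 libraries 1, 2 and 3, and to 59.7, 43.1 and 54.2 CPM with both stimuli. Monocyte and macrophage markers had positive values in 12 of 14 cases, with a median of 0.51, and 0 were called when adjusted over the list alone (camera adjusted p = 0.0215, adjusted p = 0.632 with an estimated correlation and 0.106 with the strict filter). Of 3 stroma and endothelium markers 2 were higher when adjusted over the list alone (camera adjusted p = 0.0330, adjusted p = 0.302 with an estimated correlation, 0.0676 with the strict filter and 0.0514 on log2 CPM). The other 6 marker lists had camera adjusted p values from 0.109 for neutrophils to 0.895 for dendritic cells, whose median of -0.40 and mean of -0.14 lay opposite to the direction of the camera test. Eosinophil identity genes had positive values in 20 of 25 cases, with a median of 0.36, and 1 was higher when adjusted over the list alone (camera adjusted p = 0.00221, and adjusted p = 0.395 with an estimated correlation).

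No gene was called by edgeR for both stimuli against IL-33, and 2526 genes had an unadjusted p under 0.05 where 727 are expected by chance. That number fell to 706 without libraries 2 and 3 of the combined group and to 1258 with only the groups compared. DESeq2 called 470, limma voom with quality weights 0 and edgeR without the expression filter 786. Without library 1 of the combined group edgeR called 2116, and without IL-33 library 1 it called 1. The spread estimate shared over all groups may make the main fit's p-values and SE too small in this comparison as well.

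Both stimuli against the antibody alone asked what IL-33 changed when the antibody was present. Il6 rose from 2.78 ± 0.809 to 418 ± 291 CPM (SD, n = 3) and Smpdl3b, a phosphodiesterase gene, from 1.33 ± 0.732 to 40.9 ± 21.3 CPM. Il1b, Ptgs2 and Nfkbia had log2 fold changes of 5.84, 5.67 and 2.97. Sgsh, a lysosomal sulfatase, fell from 10.6 ± 0.963 to 2.77 ± 0.987 CPM. Of 29 NF-kB pathway members and feedback genes 16 rose, and 21 when adjusted over the list alone (camera adjusted p = 1.17e-29, and adjusted p = 0.152 with an estimated correlation). Their fry p for movement on balance in 1 direction was 0.000277. Siglecf had a log2 fold change of -0.56 (edgeR adjusted p = 0.103) and Ccl17 of 2.44 (adjusted p = 0.0528). In edgeR 643 genes were called, 393 higher and 250 lower, 385 of them at least 2-fold. The count was 220, 208 higher and 12 lower, without libraries 2 and 3 of the combined group and 242, 195 higher and 47 lower, with only the 2 groups. It was 124, 138 and 206 without antibody libraries 1, 2 and 3, and 2839 and 209 without libraries 1 and 3 of the combined group. Limma voom with quality weights called 424. The spread estimate shared over all groups may make the main fit's p-values too small here too, and 643 too large.

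Among marker lists of other cells, 3 of 14 monocyte and macrophage genes rose with both stimuli against the antibody alone, and 4 when adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.0256, adjusted p = 0.651 with an estimated correlation, 0.0860 on log2 CPM and 0.151 with length and GC trends removed there). They were Spic, Hmox1 and Csf1r, with log2 fold changes of 3.97, 2.88 and 0.71. Spic kept its call whichever library was left out, while Hmox1 and Csf1r lost it in 4 and 3 of 6 such fits, and limma voom did not call Spic or Hmox1. Csf1r was also not called without libraries 2 and 3 of the combined group or with only the groups compared. Of 8 dendritic cell markers 1 rose, and 2 when adjusted over the list alone (camera adjusted p = 0.108). Of 3 stroma and endothelium markers 0 were called, and 2 were higher when adjusted over the list alone (camera adjusted p = 0.0619). No member was called in the other 6 marker lists, with camera adjusted p values from 0.172 for erythroid to 0.963 for neutrophil markers, whose median of 0.12 and mean of 0.10 lay opposite to the direction of the camera test.

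The IL-33 effect was set side by side without and with the antibody, in comparisons that share no library. Of 213 genes called higher by IL-33 alone 161 were also called higher with the antibody present, where independent lists would share 5.75. Of 109 called lower 45 were shared, where independent lists would share 1.87. Both comparisons come from 1 fit and share each gene's estimate of spread, so some overlap beyond these numbers may arise without a shared effect. Across 14547 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.409 and a Spearman correlation of 0.257. The antibody effect without and with IL-33 had a Pearson correlation of 0.00388 and a Spearman correlation of -0.0102, and with 1 library left out the first ran from -0.124 to 0.10. Jackknife SE, from leaving out each library in turn, were 0.215 and 0.298 for these correlations. They were 0.218 and 0.231 for the IL-33 effect. A repeat of the antibody effect is thus not excluded.

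The interaction asked whether the antibody effect differed with IL-33. Glycolysis and hypoxia genes had positive values in 20 of 25 cases, with a median of 0.41 (camera adjusted p = 0.000251, and adjusted p = 0.545 with an estimated correlation). Tpi1 had 1.20 (SE 0.443) and Ldha 1.08 (SE 0.333) on the log2 scale. Il6 had an interaction of 0.73 (SE 0.825), Il13 of 0.09 (SE 0.601) and Ccl3 of -0.20 (SE 0.741). No gene was called by edgeR, and 1150 had an unadjusted p under 0.05 where 727 are expected by chance. That number depended on the combined group, with 3562, 963 and 706 when its library 1, 2 or 3 was left out. DESeq2 called 3, limma voom with quality weights 0, edgeR without the expression filter 86, and edgeR without library 1 of the combined group 4.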

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

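The test with library 1 of the combined group alone and the settings that remove length and GC trends or leave out libraries 2 and 3 of that group were chosen only after the data or the result were seen. For the interaction camera called 2 gene lists at its preset correlation and 0 with an estimated correlation, so a different antibody effect with IL-33 stays open for both. Glycolysis and hypoxia genes had a camera adjusted p of 0.000251, and adjusted p = 0.545 with an estimated correlation ended the call; the fry p was 0.173. Their other settings with all libraries ran down to 5.02e-05, on log2 CPM with the length and GC trends removed. Eosinophil identity genes had a camera adjusted p of 0.0330, and other settings ran from 0.0171 with the replicate block to adjusted p = 0.545 with an estimated correlation, with a fry p of 0.201. Their call was also lost with the strict filter (0.0918), without libraries 2 and 3 of the combined group (0.102), on log2 CPM (0.0635) and on log2 CPM with the trends removed (0.307).

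Glycolysis and hypoxia genes were higher with both stimuli than with IL-33, by a median log2 fold change of 0.653. Trends on gene length and GC content are argued against as the whole cause, because the median was 0.565 with the trends removed. The camera adjusted p of the list was then 1.12e-09. Other settings with all libraries ran from 4.1e-10 with the replicate block to 0.337 with an estimated correlation. The share of libraries 2 and 3 of the combined group cannot be told apart from an effect of the combination, since library 1 alone gave 0.613 and a single library excludes nothing. By library, the list's median against the IL-33 mean was 0.589, 0.172 and 0.968 with both stimuli and 0.235, -0.196 and -0.132 with IL-33. That the combination raises these genes may be put as a hypothesis, with the libraries left open.

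Against isotype edgeR called 1437 genes with both stimuli and 322 with IL-33, but limma voom with quality weights turned the order, with 1425 against 2089. Its weights were 0.303, 0.593 and 0.379 for libraries 1, 2 and 3 of the combined group and 2.35, 0.682 and 0.645 for those of IL-33. The edgeR fit without libraries 2 and 3 of the combined group set 1 library against 3 of IL-33, so its counts do not bear on this difference. With length and GC trends removed the ratio of the edgeR counts was 3.73, which argues against those trends as the whole cause of that difference. With 1 library left in each stimulated group, the combined count was over 1.5 times the IL-33 count in 2 of 3 fits, with ratios of 1.94, 1.32 and 10.3. The part of libraries 2 and 3 of the combined group thus cannot be told apart from a larger response, and the ratio of 10.3 came from IL-33 library 3, with 122 genes. The spread estimate shared over all groups may also make 1437 too large and 322 too small. With only the groups compared the counts were 738 and 463. Whether the combination gives a larger response stays open.

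With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. They were fitted without the replicate block, so they ignore the pairing taken for IL-33 against isotype. The real split gave 322, 1437 and 643 genes for IL-33 against isotype, both stimuli against isotype and both stimuli against the antibody; the highest other split gave 0, so 1 of 10 gave as many. For the antibody against isotype the real split gave 0 and the highest other 0, and for both stimuli against IL-33 they gave 0 and 3. With a real count of 0, 10 of 10 splits give as many whatever the data, and so do 100 of 100 regroupings for the interaction, so these counts say nothing about chance. The highest other regrouping for the interaction gave 1104, which points to a structure of the samples: looked at afterwards, it was the only regrouping with all 6 libraries that got IL-33 on the same side of the contrast. Of 8 regroupings with 5 of them on a side 3 gave calls, up to 582 genes, and of 45 with 3 on each side 1 did, with 4 genes. Of 46 with 4 on a side 1 did, with 193.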

How the results depend on the processing

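No named gene or list changed direction while called, in the settings run. DESeq2 called 806, 12, 2404, 470, 1627 and 3 genes for IL-33 against isotype, antibody against isotype, both against isotype, both against IL-33, both against antibody and the interaction. At least 2-fold it called 354, 7, 142, 590 and 3, leaving out both against isotype, which moved by less than 1.5 times. Without the filter the counts were 683, 70, 786, 1600 and 86, and 387, 47, 292, 751 and 86 at least 2-fold, for those 5 comparisons. With only the groups compared they were 20 (15 at least 2-fold) for the antibody, 738 for both against isotype and 242 (215) for both against antibody. Gene counts stayed within 1.5 times with 2 other scalings and the strict filter. The cause was not tested.

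Leaving out 1 library gave 116 to 488 genes (105 to 370 at least 2-fold) for IL-33 against isotype, 0 to 0 for the antibody, 515 to 2916 (410 to 1400) for both against isotype and 0 to 2116 (0 to 894) for both against IL-33. It gave 124 to 2839 (116 to 1294) for both against antibody and 0 to 4 (0 to 4) for the interaction. The correlation of IL-33 effects ran from 0.310 to 0.515 (Spearman 0.154 to 0.363) and of antibody effects from -0.124 to 0.10 (Spearman -0.160 to 0.168).

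The settings of this paragraph were chosen after seeing the data. Without libraries 2 and 3 of the combined group, the lone library assumed to vary like the other groups, 688, 1 (1 at least 2-fold), 651 and 220 (198) genes were called for IL-33, antibody, both against isotype and both against antibody. Limma voom with weights called 2089 (669), 10 (7) and 424 for IL-33, antibody and both against antibody. The 9-library fit called 755 and 1 (1) for IL-33 and antibody. For IL-33 against isotype the replicate block with only the groups compared called 1235 (429), and removal of length and GC trends 489, or 550 with the replicate block.

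In the fit of 12 libraries the replicate block called 364 genes for IL-33 against isotype, 1459 for both against isotype and 642 for both against antibody. Same-numbered libraries of the other comparisons did not all pass the threshold, with correlations from -0.23 to 0.27, which does not exclude a pairing there. Under the block 12 calls of named genes and no list call were lost. Lists called fell to 0 in each comparison with an estimated correlation. The strict filter left 7 lists for both against IL-33 and 1 for the interaction, where 7 were called without libraries 2 and 3 of the combined group and 1 on log2 CPM. At this depth Csf2 could not be tested.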

Other observations

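The 9-library fit, the fry test of 20 genes and their count without libraries 2 and 3 of the combined group were tests chosen only after the result was seen. Cholesterol synthesis and uptake genes were higher with both stimuli than with the antibody alone. Of 20 members 5 rose, and 11 when adjusted over the list alone (camera adjusted p = 4.38e-07, and adjusted p = 0.396 with an estimated correlation). The median log2 fold change was 0.85, with 18 of 20 members positive. Of the members that rose, Insig1, Cyp51 and Fdft1 each lost the call in 4 of 6 fits with 1 library left out and Idi1 in 5, and limma voom with quality weights called none of these 4. Without libraries 2 and 3 of the combined group, which stood apart, Insig1, Cyp51 and Fdft1 were not called. For IL-33 alone against isotype 1 of the 20 rose, and 6 when adjusted over the list alone (camera adjusted p = 0.000312, and adjusted p = 0.596 with an estimated correlation). For movement on balance in 1 direction, this list had a fry p of 0.0303 with both stimuli against the antibody and 0.147 with IL-33 against isotype. Ribosome biogenesis genes and MYC targets rose with both stimuli against isotype in 7 of 26 cases, and in 12 when adjusted over the list alone (camera adjusted p = 1.53e-06, and adjusted p = 0.299 with an estimated correlation). Of these Nop16, Nme1, Rrp12 and Rrp9 lost their calls without libraries 2 and 3 of the combined group, whose ribosomal protein genes took 3.23% and 3.70% of the counts. Proliferation genes had 0 of 20 members called with both stimuli against isotype by edgeR (camera adjusted p = 0.565). The fry p for movement on balance in 1 direction was 0.000517 for ribosome biogenesis genes and MYC targets and 0.794 for proliferation genes.

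When the isotype and antibody groups were fitted by themselves, edgeR called 20 genes, 16 higher and 4 lower. The genes named here were chosen after their values were seen. Spred1, Spred2 and Dusp6, feedback inhibitors of the ERK pathway, had log2 fold changes of 1.46 (SE 0.173), 1.33 (SE 0.116) and 0.94 (SE 0.111). Etv5, a transcription factor, had 1.73 (SE 0.194) and Tnf, which encodes tumour necrosis factor, 1.20 (SE 0.120). Bbc3, which encodes the pro-apoptotic protein PUMA, had -0.87 (SE 0.119). In the fit of 12 libraries none was called, and Spred1 and Dusp6 had an edgeR adjusted p of 0.265.

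The spread of the combined group's libraries is argued against as the whole reason that these calls were lost, since the 9-library fit without that group called 1 of the 20, though genes with an unadjusted p under 0.05 went from 370 to 767 in it. Chance selection was looked at in both stimuli against IL-33, which shares no library with the fit that gave the genes. There 20 of 20 genes kept their direction, also without libraries 2 and 3 of the combined group. Since such genes move together (mean correlation within groups 0.359), the set was tested by fry, which allows for this (p = 0.00961). That test shares 1 estimate of spread over all groups although the combined group's libraries varied more, so its p may be too small. Chance selection thus stays open, although the direction was repeated. Without IL-33 library 3, which responded more weakly, 19 of 20 kept their direction, with the median size at 0.487 in place of 0.765. The fry test was not run without that library, and the genes move together, so the part of its weaker response stays open. Whether the antibody raises ERK output more widely stays open. Of 10 further genes listed before the test 5 were measured, 2 of them positive. Their mean log2 fold change was 0.115 and their fry p was 0.500. Ccnd1, Epha2 and Spry2 had means of only 1.18, 0.889 and 0.574 CPM, so the test could show little. Phlda1 and Dusp7, at 5.17 and 19.4 CPM, had log2 fold changes of 1.165 and -0.232. Engaging Siglec-F may thus shift a small set of genes, a hypothesis found and tested on the same data.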
